A study of Mus musculus with 17 samples.

How the data were processed

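RNA from 17 cultures of 32D, a mouse myeloblast-like cell line that needs IL-3 to grow, was measured on Affymetrix Mouse Exon 1.0 ST arrays, which carry probe sets for single exons. The arrays fell into 5 groups: parental cells (2 arrays), cells with the empty pLXRN retroviral vector (2), cells with human wild-type FLT3 (2), cells with wild-type FLT3 grown with FLT3 ligand (2), and cells with human FLT3 carrying an internal tandem duplication (ITD), a class of activating mutation of leukaemia (9). Each of the 9 ITD arrays came from a different mutant, and the lines are numbered here 1 to 9. The vector, wild-type and mutant lines were transduced as populations of many clones. Per the growth protocol, the 4 control groups grew with mouse IL-3 at 1 ng/mL, the ligand group received FLT3 ligand at 20 ng/mL, and the ITD lines grew without IL-3. The protocol does not say outright that IL-3 stayed in the cultures with ligand, and without it the ligand contrast would also hold the absence of IL-3. The label of the ligand group can be read as a line transduced with the ligand, and the growth protocol was followed. The sample titles call the 2 arrays of a control group biological replicates. The sources used here do not settle whether these came from separately made lines or from cultures of 1 line. The spread within a pair may therefore be technical or only that between cultures.

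The deposited values were log2 signals per probe set, which the authors made with RMA in Affymetrix Expression Console 1.1, per the submitters' processing notes. RMA subtracts background, normalises between arrays and summarises the probes of a probe set. Neither the genome build nor the probe set filter was stated in the sources used here, so no coordinates are given. The table held 1256831 probe sets, of which 20744 were exactly 0 on all 17 arrays and carried no gene symbol. Array medians over all probe sets lay between 4.63 and 4.69 (log2), and the number of arrays limits the precision.

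The gene annotation of the platform gave a symbol to 325444 probe sets, and 6684 of these had several symbols and were left out. The 931387 probe sets without a symbol in that annotation were not analysed here. Symbols were updated through the synonyms of a RefSeq table, where 18006 of 22296 symbols were current, 4227 were changed and 63 could not be matched and were kept. A probe set was used when its mean over the 17 arrays was above 4.599, the median of that mean over all probe sets, and 237584 probe sets passed. The value of a gene was the mean of its used probe sets, which gave 20227 genes with a median of 9 probe sets and 1987 genes with 1.

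Group means were fitted for all genes with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend), with 1 mean for each of the 5 groups, 12 residual degrees of freedom and 4.49 prior degrees of freedom. The 6 contrasts, tested two-sided, were ITD minus the unweighted mean of the parental, vector and wild-type groups, ITD minus wild-type, ITD minus wild-type with ligand, wild-type with ligand minus wild-type, wild-type minus vector, and vector minus parental. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes, and log2 differences are given with the standard error (SE) of the fit. All groups share 1 spread, to which the 9 different mutants contribute 8 of the 12 degrees of freedom. Variation among the ITD lines was tested one-sided by an F ratio of the variance over the 9 ITD arrays (8 degrees of freedom) to the pooled variance within the 4 control pairs (4 degrees of freedom). Because each mutant had 1 array, no single mutant was tested.

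The 21 gene lists were primary granule, late granule and mature neutrophil, myeloid transcription factors, STAT5 targets, ERK feedback, mast cell and basophil, monocyte and macrophage, erythroid and megakaryocyte, lymphoid and plasmacytoid, cytokine receptors, cell cycle, cyclin-dependent kinase inhibitors and G1 cyclins, apoptosis regulators, glycolysis, cholesterol synthesis, amino acid response, interferon response, MHC class II, chemokines and cytokines, Wnt pathway, and handling stress. Each list was tested with camera of limma against all other genes at a preset correlation of 0.01 between genes, adjusted over the 21 lists, and again with an estimated correlation. Flt3 was named in every comparison. For the first 3 contrasts the 12 largest rises and 12 largest falls were named among called genes whose every ITD array lay beyond every control array, and for the other 3 contrasts the 8 largest of each direction among called genes without overlap. Among genes called for variation the 20 with the largest SD over the ITD arrays were named. Also named were up to 2 genes per line and direction more than 1 (log2) from the other lines and beyond all 16 other arrays. From each list up to 4 members called in the first contrast were named. Predicted gene models were passed over. The groups, tests, lists, naming rule and all alternatives not named below as added were fixed before the data were examined, and any other gene named was chosen after its values were seen.

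The alternatives were no filter and a stricter filter on dim probe sets, the median of probe sets, genes with at least 3 probe sets, quantile normalisation again, centring on array medians, array weights by kind of array, robust variance without a trend, a replicate block, a 2-fold threshold, other control sets, only the control groups, another reference spread for variation, an estimated correlation and fry for the lists, and leaving out each array in turn. When leaving out an array left a group with 1 array, that array was assumed to vary like the other groups. The replicate numbers 1 and 2 were shared by the control groups, but the deviations of arrays with the same number correlated between -0.118 and 0.092 across genes, so the number was not taken as a pairing. Alternatives with parental and vector cells alone for the lists, without the vector line, without the parental line, with lines as units, with crossed replicate numbers and without ITD lines 4 and 7 were added after seeing the data. Relations across the 17 arrays were tested with 100000 permutations and relations across the 9 ITD lines with exact permutation tests, both two-sided.

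The procedure was tested on simulated data in which 200 genes were changed on a background of the measured spread. Simulated control lines had the same mean for each gene and differed only by the spread within pairs. In the measured data the median SD was 0.173 between control line means and 0.124 within pairs. The recovery and false calls therefore do not cover differences between control lines. The contrast of ITD with the 3 control groups recovered 73.1% of the genes changed 1.5-fold and 97% of those changed 2-fold, with 6 false calls. The ligand contrast recovered 65.7% of the genes changed 2-fold, with 18 false calls. The test of variation recovered 18.2% of the genes whose ITD standard deviation was 10 times the pair value and 0% at 3 times, so it finds few of the varying genes.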

Results

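Gene expression was compared on 17 exon arrays of 32D cells: 2 of parental cells, 2 of cells with the empty vector, 2 with wild-type FLT3, 2 with wild-type FLT3 and FLT3 ligand, and 9 with different FLT3/ITD mutants. FLT3 is a receptor tyrosine kinase of early blood cells. The series asked how the mutants change expression and how variable they are. Gene profiles correlated with a median r of 0.984 within control pairs, 0.977 between ITD lines and 0.963 between ITD and control arrays, each across genes, which are not independent replicates. Control groups correlated with each other at a median of 0.965, so the control lines differed among themselves about as much as they differed from the ITD lines.

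Flt3 itself reported the transgene. Its mean log2 value was 5.25 in parental cells, 5.19 with the vector, 6.76 with wild-type FLT3 (n = 2 each) and 7.16 with ITD (n = 9), and every ITD line lay between 7.08 and 7.32. The introduced receptor was human and the probe sets were designed for mouse, and 6 of the 30 Flt3 probe sets were higher on every array with wild-type FLT3 or ITD than on every parental and vector array. The largest of these differences was 8.78 (log2) for ITD. The gene value, a mean over probe sets, therefore understates the transgene level, and ITD exceeded wild-type by 0.39 ± 0.09 (adjusted p 0.0108) and wild-type with ligand by 0.27 ± 0.09 (adjusted p 0.0858, not called).

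The comparison of ITD with the 3 control groups grown with IL-3 asked how mutant lines that grew without IL-3 differed in the myeloid programme. Neutrophil and monocyte genes fell on the ITD arrays (n = 9) against the controls (n = 6, with 2 arrays in each of the 3 groups). The SEs and p-values of this contrast rest on the spread within groups and leave out the differences between the 3 control groups. S100a9, a subunit of calprotectin, fell by 2.18 ± 0.24 (log2, SE), the complement gene C3 fell by 2.54 ± 0.31, the chitinase-like gene Chil1 fell by 2.36 ± 0.15, and Ankrd22 fell by 2.67 ± 0.20. The transcription factor gene Egr1 rose by 1.61 ± 0.10, Dusp4, whose product is a phosphatase that inactivates MAP kinases, by 1.40 ± 0.17, and Flt3, which reads the transgene, by 1.42 ± 0.06. In all, 3917 genes were called, 2269 higher and 1648 lower, and of the 167 that changed at least 2-fold 128 were lower. Only 235 genes were called in the same direction against each of the parental, vector and wild-type lines, 79 of them higher and 156 lower.

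Of the 21 measured late granule and mature neutrophil genes 13 fell and 1 rose, the same counts as when adjusted over the list alone (camera adjusted p 1.66e-07, and 0.0491 with an estimated correlation). Ly6g, a surface marker of mouse neutrophils, fell by 2.54 ± 0.24 to an ITD mean of 4.66, near background, S100a8 fell by 1.65 ± 0.27, and Ltf, the gene of lactoferrin, fell by 1.42 ± 0.32. Ly6g was already low in the wild-type line, at 5.46 against 8.07 in both parental and vector cells. Of 9 primary granule genes 5 fell, also when adjusted over the list alone (camera adjusted p 3.66e-05, but adjusted p 0.17 with an estimated correlation), and against wild-type FLT3 alone the list median was 0.182 (adjusted p 0.75). They included the lysozyme genes Lyz2, which fell by 1.31 ± 0.12, and Lyz1, which fell by 0.96 ± 0.09, the myeloperoxidase gene Mpo, which fell by 0.88 ± 0.18, and Prss57, which fell by 0.70 ± 0.15. Among the largest falls outside these lists, the haptoglobin gene Hp fell by 2.08 ± 0.21, the protease inhibitor gene Slpi fell by 2.07 ± 0.18, Trem1 fell by 1.95 ± 0.21, and the lectin gene Clec4b2 fell by 2.51 ± 0.20 to an ITD mean of 4.76, near background.

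Of 18 monocyte and macrophage genes 10 fell and none rose (11 fell adjusted over the list alone; camera adjusted p 6.46e-06, and 0.0491 with an estimated correlation). The protease gene Ctss fell by 1.98 ± 0.31 against the mean of the controls, but it averaged 5.23 in parental cells, 9.82 with the vector, 9.69 with wild-type FLT3 and 6.27 with ITD. Adgre1, which encodes the macrophage marker F4/80, fell by 1.59 ± 0.23, and Mpeg1 fell by 1.36 ± 0.19. Among 18 chemokines and cytokines 10 fell and 1 rose (11 and 1 adjusted over the list alone; camera adjusted p 4.8e-06, and 0.0491 with an estimated correlation): Ccl3 fell by 2.08 ± 0.34, Ccl4 fell by 1.53 ± 0.17, Ccl5 fell by 1.33 ± 0.13, and the receptor gene Ccr1 fell by 1.54 ± 0.29. Of 16 interferon response genes 11 fell (12 adjusted over the list alone; camera adjusted p 1.66e-07, and adjusted p 0.0591 with an estimated correlation), among them Irf7 (-0.95 ± 0.16) and Rsad2 (-0.96 ± 0.16). These genes were high in the vector line, and without that line the list median changed from -0.486 to -0.0625 and its adjusted p was 0.455, while Rtp4, at -1.05 ± 0.27, turned to 0.327.

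ERK feedback genes, which MAP kinase signalling induces and some of which restrain it, rose in 7 of 15 cases and fell in 1 (8 and 2 adjusted over the list alone, camera adjusted p 0.000114, and 0.0491 with an estimated correlation). Etv5 rose by 1.12 ± 0.10 and Dusp6 by 0.87 ± 0.10, yet both were as high in the wild-type line as with ITD: Dusp6 averaged 8.71 in parental cells, 8.85 with the vector, 10.28 with wild-type FLT3 and 10.15 with ITD. Of 15 STAT5 targets 5 rose and 1 fell (6 and 1 adjusted over the list alone; camera adjusted p 0.0214, but adjusted p 0.0591 with an estimated correlation and 0.388 without the parental line). Id1 rose by 0.71 ± 0.10, Osm by 0.59 ± 0.13 and the survival gene Bcl2l1 by 0.57 ± 0.09, while the repressor Bcl6 fell by 1.26 ± 0.19. Of 21 cell cycle genes 8 rose and none fell (12 adjusted over the list alone; camera adjusted p 1.48e-05, but adjusted p 0.256 with an estimated correlation), among them Ccne2 by 0.72 ± 0.15, Bub1 by 0.49 ± 0.12 and Cdk1 by 0.36 ± 0.07. Of 15 amino acid response genes 8 rose and 2 fell (9 and 2 adjusted over the list alone; camera adjusted p 1.72e-05, but adjusted p 0.114 with an estimated correlation). Psat1 of serine synthesis rose by 0.73 ± 0.05, the folate enzymes Shmt2 and Mthfd2 by 0.67 ± 0.08 and 0.65 ± 0.08, and Pycr1 of proline synthesis, outside the list, by 1.02 ± 0.10. The amino acid response list mean, minus that of the controls, was 0.48 on both wild-type arrays, within the 0.14 to 0.61 of the ITD arrays. The STAT5 list mean was 0.23 and 0.20 on the wild-type arrays, within the -0.03 to 0.30 of the ITD arrays.

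The other 12 lists were not called as lists. Myeloid transcription factors went both ways, with 10 of 25 risen and 7 fallen (camera adjusted p 0.358): Egr2 rose by 1.25 ± 0.17, while Cebpd fell by 1.28 ± 0.14 and Id2 fell by 1.27 ± 0.15. Mast cell and basophil genes also divided (3 of 18 rose and 5 fell, or 3 and 6 adjusted over the list alone; adjusted p 0.144), with Prss34, a basophil protease gene, up by 1.76 ± 0.28 while Cd200r3 fell by 2.23 ± 0.32 to an ITD mean of 4.87, near background. Of 13 erythroid and megakaryocyte genes 3 rose (adjusted p 0.0657): Klf1 by 1.00 ± 0.19, Itga2b by 0.75 ± 0.13, and Gata1 by 0.73 ± 0.20, which turned to -0.0848 against parental and vector cells only. Among 15 cytokine receptors Flt3 rose and 4 fell (adjusted p 0.115), including the G-CSF receptor Csf3r, which fell by 0.97 ± 0.20, the M-CSF receptor Csf1r, which fell by 0.71 ± 0.06, and the IL-3 receptor gene Il3ra, at -0.28 ± 0.09 but 0.0782 without the parental line. The lymphoid and plasmacytoid list had 1 fallen gene of 15, Siglech at -0.29 ± 0.10, and 0 adjusted over the list alone (adjusted p 0.119). Of 10 cyclin-dependent kinase inhibitors and G1 cyclins only Ccnd2 rose, by 0.34 ± 0.07 (list adjusted p 0.836).

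Among 15 apoptosis regulators 2 rose and 3 fell (2 and 4 adjusted over the list alone; adjusted p 0.56), with a median of 0.041, a mean of -0.022 and a test pointing down. Bcl2, which protects from apoptosis, rose by 0.50 ± 0.13, and the death-promoting genes Bmf (-0.44 ± 0.09) and Bak1 (-0.39 ± 0.07) fell. Of 18 glycolysis genes 3 rose and 3 fell (adjusted p 0.836), with Pfkp up by 0.44 ± 0.08 while the lactate transporter gene Slc16a3 fell by 0.68 ± 0.10. Of 17 cholesterol synthesis genes 2 rose and 4 fell (2 and 5 adjusted over the list alone; adjusted p 0.0738), with Idi1 up by 0.71 ± 0.16 while Hmgcs1 fell by 0.71 ± 0.10. Of 7 MHC class II genes 2 fell (adjusted p 0.0592), H2-DMb1 (-0.55 ± 0.09) and H2-Aa (-0.37 ± 0.12). In the Wnt pathway list, with a median of -0.02, a mean of 0.049 and a test pointing up, Myc alone of 13 genes rose, by 0.61 ± 0.07 (list adjusted p 0.668). Handling stress genes, a marker of sample treatment, went both ways (3 of 12 rose and 3 fell, adjusted p 0.742; median -0.002, mean 0.046), with Egr1 up and Hmox1 (-0.66 ± 0.17), Dusp1 (-0.62 ± 0.13) and Fosb (-0.53 ± 0.08) down. In the glycolysis, erythroid, cytokine receptor, MHC class II, handling stress, myeloid transcription factor, kinase inhibitor and Wnt lists the number of called genes was the same adjusted over the list alone.

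Ptgs2, the inducible prostaglandin synthase, was 1.60 ± 0.29 higher with ITD but stood at -0.0181 under the stricter filter on dim probe sets. The remaining large rises named by the rule were the potassium channel gene Kcnk5 (1.24 ± 0.16), the carbonic anhydrase gene Car12 (1.21 ± 0.12), Vmn1r4, Zfp97, Luzp1 and Hemgn, together with Trav6d-6, which rested on 1 probe set, and the remaining large falls were P2ry13, Cd200r2, and Clec4a4 and Pilrb1 with 1 probe set each. Not every call held against each control line: the ITD mean lay above the lowest control group mean for Ctss, Ccr1, Irf7, Rtp4, Hmox1, Prss57 and Il3ra, and below the highest for Prss34, Klf1, Gata1, Itga2b, Etv5, Dusp6, Mthfd2 and Ccnd2. All 9 ITD arrays lay outside the range of the 3 control line means for 842 genes, 787 of them called, where chance over splits of 12 lines gives 0.909% of genes, or 184. The design did not separate the mutant receptor from the absence of IL-3. The count also rested on which control lines were used: it was 2491 without the vector line, and 466 genes, 44.2% of them higher, were called when the 12 lines were the units of replication.

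**Figure D1:**
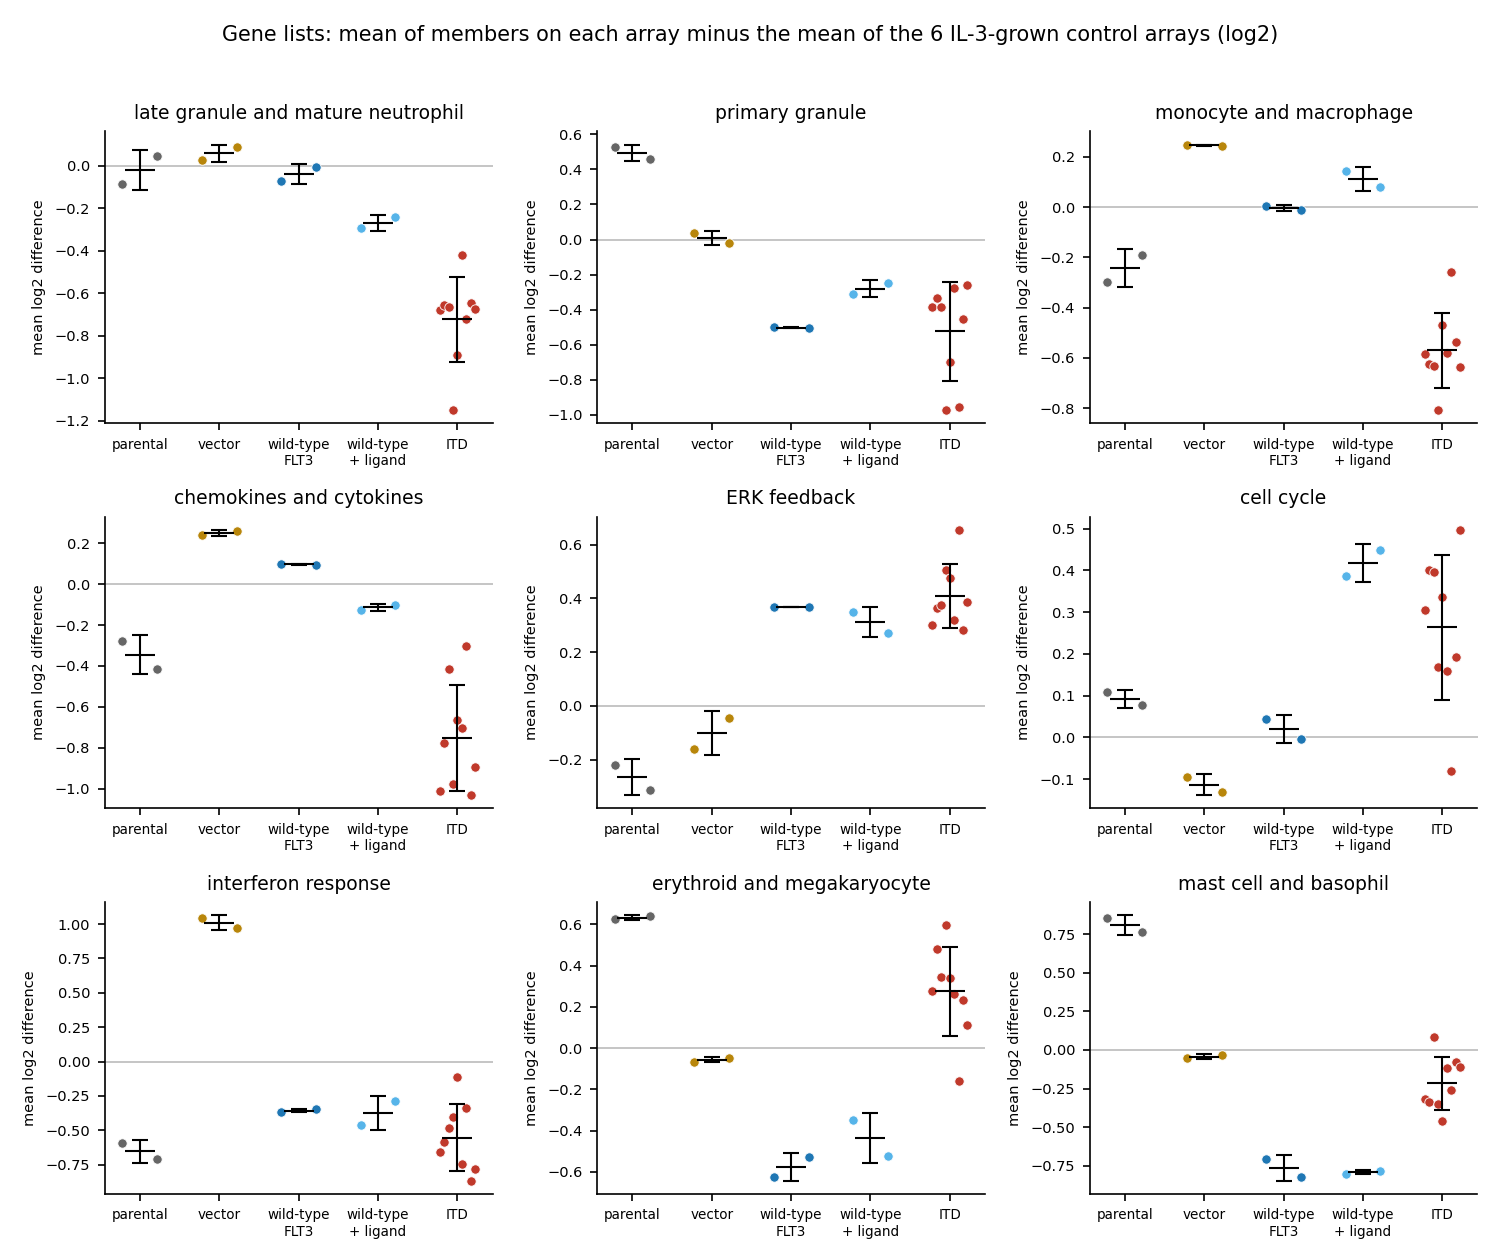
Mean over the measured members of 9 gene lists on each array, minus the mean of the 6 IL-3-grown control arrays (vertical axis, log2), by group (horizontal axis); points are arrays and bars the group mean ± SD. The late granule list lay between -1.15 and -0.42 on the ITD arrays, below every control array, the primary granule list was at -0.50 on both wild-type arrays, within the range of the ITD arrays, and the interferon list was high on both vector arrays (1.05 and 0.97).

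**Figure D2:**
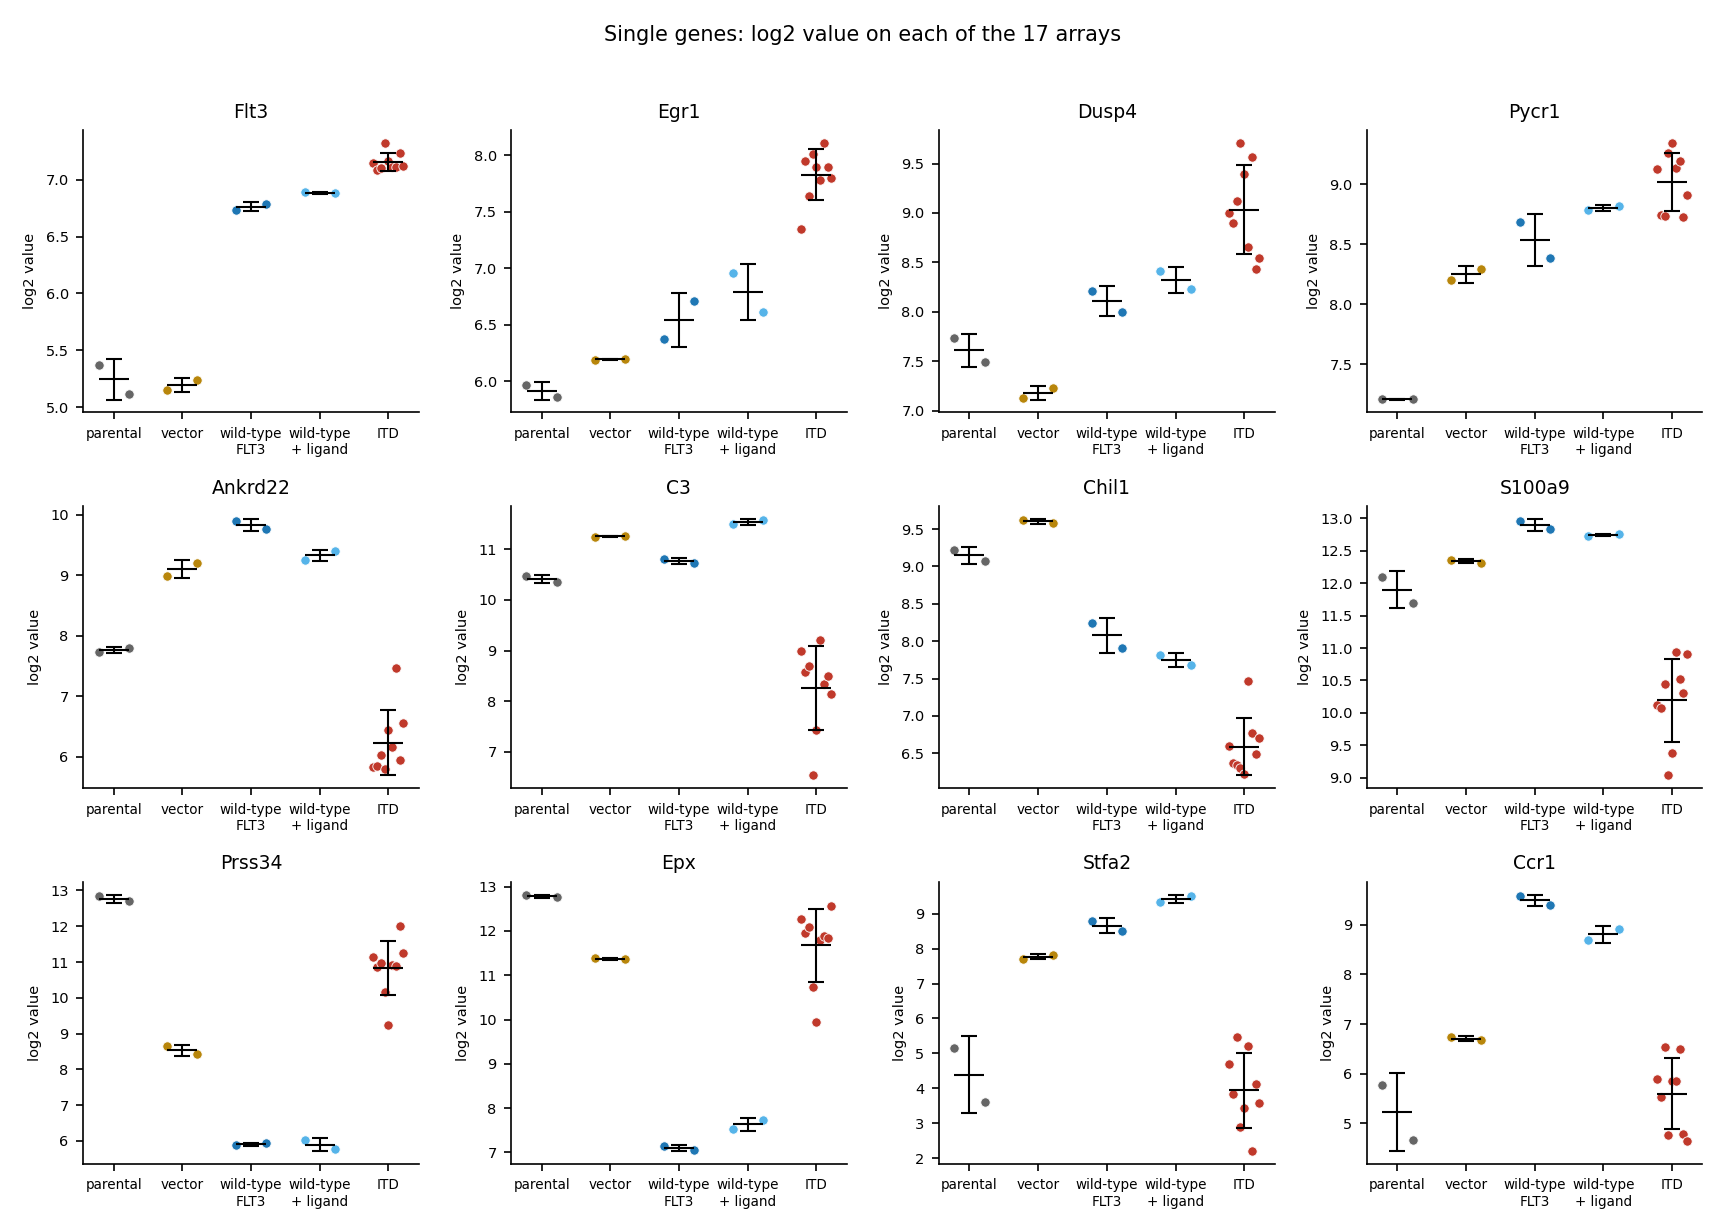
Log2 values of 12 genes (vertical axes) on the 17 arrays by group (horizontal axes); points are arrays and bars the group mean ± SD. Flt3 lay between 7.08 and 7.32 on the 9 ITD arrays, and Prss34 and Epx were lowest in both wild-type FLT3 groups while Stfa2 and Ccr1 were highest there.

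ITD was then compared with the normal receptor. The largest rises with ITD (n = 9) over wild-type FLT3 (n = 2) were those of Prss34, by 4.93 ± 0.42, the eosinophil peroxidase gene Epx by 4.58 ± 0.45, and Prg2 and Prg3, the genes of major basic protein and its homologue, by 4.30 ± 0.66 and 3.38 ± 0.60, where Prg3 averaged 4.52 with wild-type FLT3, near background. The transcription factor genes Klf1 and Gata1 rose by 2.39 ± 0.28 and 2.35 ± 0.29, the growth factor gene Angpt1 by 2.92 ± 0.22, and the tetraspanin gene Cd9 by 2.69 ± 0.14. Stfa2 and Csta3, which encode inhibitors of cysteine proteases, were lower, at -4.72 ± 0.62 and -4.05 ± 0.40. Stfa2, with 1 probe set, averaged 3.94 with ITD, below the 4.599 that a probe set mean had to exceed, and Csta3 averaged 4.81, so the sizes of these falls rest on values near background. Further falls were those of Ccr1 (-3.89 ± 0.43), Ctss (-3.43 ± 0.46), Trem1 (-3.29 ± 0.32) and Clec5a (-3.16 ± 0.41). For many of these genes it was the wild-type line that stood apart from parental cells. Prss34 averaged 12.77 in parental cells, 8.54 with the vector, 5.90 with wild-type FLT3 and 10.83 with ITD, and Ccr1 averaged 5.22, 6.71, 9.49 and 5.60 in the same order.

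In this contrast 1559 genes were called, 661 higher and 898 lower, and the share of higher genes turned from 42.4% to 51.9% after quantile normalisation again. Of 13 erythroid and megakaryocyte genes 5 rose (7 adjusted over the list alone; camera adjusted p 3.57e-06, and 0.0207 with an estimated correlation), and of 25 myeloid transcription factors 9 rose and 5 fell (11 and 5 adjusted over the list alone; adjusted p 0.000344, and 0.0168 with an estimated correlation). Of 21 late granule and mature neutrophil genes 10 fell (11 adjusted over the list alone; adjusted p 8.27e-05, but adjusted p 0.0877 with an estimated correlation), among them S100a9 (-2.70 ± 0.35). Of 18 monocyte and macrophage genes 5 fell (10 fell and 1 rose adjusted over the list alone; adjusted p 0.00108, but adjusted p 0.105 with an estimated correlation), and of 18 mast cell and basophil genes 4 rose (5 rose and 1 fell adjusted over the list alone; adjusted p 0.00264, but adjusted p 0.0634 with an estimated correlation). The cell cycle, MHC class II and chemokine lists were also called, at 0.000237, 0.0154 and 0.00402, with adjusted p of 0.499, 0.214 and 0.214 at an estimated correlation. The STAT5 target list did not differ, with no gene of 15 called (median -0.026, camera adjusted p 0.75). Of 15 amino acid response genes 1 rose and 1 fell (median -0.107, camera adjusted p 0.658). ERK feedback genes did not differ as a list either (adjusted p 0.599): Dusp6 differed by -0.13 ± 0.15 (adjusted p 0.667) and Etv5 by -0.08 ± 0.14 (adjusted p 0.811). Egr1, by contrast, rose by 1.28 ± 0.15. The call rested on both wild-type arrays, with 308 genes without the first and 281 without the second, and 2463 genes were called without ITD line 7.

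Against wild-type FLT3 with ligand (n = 2) 1173 genes were called, 347 higher and 826 lower. Prss34 rose by 4.93 ± 0.42, Prg2 by 4.70 ± 0.66, Epx by 4.04 ± 0.45, the granzyme gene Gzmb by 3.44 ± 0.56 and the mast cell carboxypeptidase gene Cpa3 by 2.76 ± 0.25. Among the falls were Stfa2 (-5.49 ± 0.62) and Csta3 (-4.95 ± 0.40), against the same ITD values near background, C3 (-3.27 ± 0.45) and Ccn3 (-3.16 ± 0.21). Of 13 erythroid and megakaryocyte genes 5 rose (7 adjusted over the list alone; adjusted p 2.46e-05, and 0.0343 with an estimated correlation), and of 18 mast cell and basophil genes 4 rose (5 rose and 1 fell adjusted over the list alone; adjusted p 0.000253, and 0.0343 with an estimated correlation). Of 18 monocyte and macrophage genes 5 fell (10 adjusted over the list alone; adjusted p 8.55e-05, but adjusted p 0.0583 with an estimated correlation). The late granule, myeloid transcription factor and chemokine lists were called at 0.0146, 0.0247 and 0.014, with adjusted p of 0.33, 0.0583 and 0.33 at an estimated correlation. The share of called genes that were higher was 29.6%, and 45.6% after quantile normalisation again, and the count was 243 or 245 without the first or the second ligand array.

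The addition of ligand to wild-type FLT3 (2 arrays against 2) gave no called gene in the fit of all arrays, where limma found 1555 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.141. Cell cycle genes were higher as a list, with a median of 0.374 over 21 genes (camera adjusted p 1.79e-11, but adjusted p 0.354 with an estimated correlation), and 4 of them were called adjusted over the list alone. Flt3 averaged 6.76 without and 6.89 with ligand. The spread of this fit came largely from the 9 different mutants, and with the 4 control groups alone limma called 1148 genes, 851 higher and 297 lower. The spread of the second fit came only from the control pairs and may be technical. The count and SEs of that fit may therefore be too favourable. In that fit 15 of the 21 cell cycle genes rose (adjusted p 1.29e-17, but adjusted p 0.118 with an estimated correlation). Of the other 20 lists 7 were also called there. The handling stress list, the marker of sample treatment, was lower, with 3 of 12 genes fallen and a median of -0.222 (adjusted p 0.0131, but adjusted p 0.25 with an estimated correlation), and in the late granule list 5 of 21 genes fell and 1 rose (adjusted p 0.000838, but adjusted p 0.13 with an estimated correlation). The primary granule, myeloid transcription factor, cytokine receptor, cholesterol synthesis and MHC class II lists were called at 0.00624, 0.00624, 0.0353, 0.0258 and 0.0306, with adjusted p of 0.314, 0.259, 0.314, 0.364 and 0.259 at an estimated correlation. The genes named next were chosen after these values were seen. The lectin gene Cd209c rose by 2.64 ± 0.11, the serine protease inhibitor gene Serpina3f by 2.51 ± 0.10, Serpina3g by 1.59 ± 0.07, and the thymidine kinase gene Tk1, which serves DNA synthesis, by 1.19 ± 0.06. The transglutaminase gene Tgm2 fell by 1.30 ± 0.05 and Avil fell by 1.16 ± 0.07.

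The wild-type receptor was compared with the empty vector (2 arrays each, both with IL-3), which gave 1662 called genes, 1113 higher and 549 lower. Each pair may come from 1 line, so the receptor cannot be told apart from other differences between the lines. Vector and parental cells, neither with the receptor, already differed in 451 genes. Traits of the wild-type line also enter the contrasts of ITD with wild-type FLT3, without and with ligand. Flt3 rose by 1.57 ± 0.11. ERK feedback genes rose in 5 of 15 cases (7 adjusted over the list alone; camera adjusted p 0.0013, but adjusted p 0.0814 with an estimated correlation), with Etv5 up by 1.52 ± 0.18 and Dusp6 by 1.43 ± 0.20. Of 15 amino acid response genes 7 rose (9 adjusted over the list alone; adjusted p 0.000106, but adjusted p 0.176 with an estimated correlation), including Trib3 by 1.47 ± 0.38 and Mthfd2 by 0.82 ± 0.16. The largest rises also included Ccr1 (2.78 ± 0.55), Ccn3 (2.44 ± 0.27) and the TNF family ligand gene Tnfsf9 (2.26 ± 0.16).

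The eosinophil granule genes Epx (-4.27 ± 0.58) and Prg2 (-3.11 ± 0.84) fell in the wild-type line. Of 18 mast cell and basophil genes 5 fell (1 rose and 5 fell adjusted over the list alone; adjusted p 3.03e-05, and 0.0101 with an estimated correlation), and of 25 myeloid transcription factors 6 fell and 1 rose (9 and 1 adjusted over the list alone; adjusted p 3.03e-05, and 0.00477 with an estimated correlation). Interferon response genes fell in 10 of 16 cases (13 adjusted over the list alone; adjusted p 6.17e-16, and 0.0101 with an estimated correlation), among them Rtp4 (-3.68 ± 0.51) and Usp18 (-3.13 ± 0.51). For the interferon genes it was the vector line that stood apart. Their list median above parental cells was 1.613 with the vector and 0.324 with wild-type FLT3. The erythroid, primary granule, monocyte and cholesterol lists were called at 0.00133, 0.000605, 0.0423 and 0.0485, with adjusted p of 0.0899, 0.27, 0.273 and 0.427 at an estimated correlation. Higher genes made up 67% of the calls, and 51.3% after quantile normalisation again. Without the first or second vector array 516 or 503 genes were called, and without the first or second wild-type array 456 or 599.

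Vector cells differed from parental cells in 451 genes, 257 higher and 194 lower (2 arrays each), although neither carried the receptor and Flt3 differed by -0.05 ± 0.11 (adjusted p 0.893). Interferon response genes rose in 9 of 16 cases (14 adjusted over the list alone; camera adjusted p 1.28e-22, and 0.00416 with an estimated correlation), with Rtp4 up by 4.57 ± 0.51, the antiviral gene Oas2 by 3.07 ± 0.25 and the regulator Irf7 by 2.53 ± 0.31. The antigen presentation genes Ctss and Cd74 rose by 4.60 ± 0.59 and 3.99 ± 0.76. Of 18 mast cell and basophil genes 4 fell, also adjusted over the list alone (adjusted p 1.02e-06, and 0.00416 with an estimated correlation): Prss34 fell by 4.23 ± 0.54 and Cpa3 fell by 2.20 ± 0.32. Outside the list Prss28 (-4.35 ± 0.43), Prg3 (-4.12 ± 0.76) and Lrrc19 (-5.32 ± 0.48) fell, the last to a vector mean of 4.36, near background.

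Of 17 cholesterol synthesis genes 1 fell in the vector line over all genes and 11 adjusted over the list alone (adjusted p 1.12e-08, but adjusted p 0.0588 with an estimated correlation). Of 15 amino acid response genes 2 rose (5 adjusted over the list alone; adjusted p 3.21e-06, but adjusted p 0.09 with an estimated correlation). The erythroid, cell cycle, STAT5, monocyte and chemokine lists were called at 0.000521, 0.000521, 0.00667, 0.0103 and 0.00667, with adjusted p of 0.0588, 0.399, 0.0512, 0.182 and 0.198 at an estimated correlation. Higher genes made up 57% of the calls, and 44.7% with array medians centred. Without the first or second parental array 149 or 126 genes were called, without the first or second vector array 105 or 133, and without ITD line 7 764.

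The series also asked how much the ITD mutants vary. Eif2s3y, a Y-linked translation factor gene, ranged from 3.59 in line 4 to 10.06 in line 6 (SD 2.50 over 9 lines, against 10.68 and 10.69 on the parental arrays). Il2ra, a receptor subunit of IL-2, ranged from 5.32 in line 9 to 10.76 in line 1 (SD 1.63), and the semaphorin gene Sema7a was highest in the same line, at 9.73 (SD 1.37). Fcer1a, the high-affinity IgE receptor subunit, was 7.31 in line 5 and 11.97 in line 9 (SD 1.58). Cd74, the MHC class II invariant chain, was 9.95 in line 7 and between 6.53 and 7.997 in the others. Serpina3f, Serpina3g and Akr1c19, with SDs from 1.04 to 1.71, were also among the genes that rose with ligand when the control groups alone were fitted. The other genes named for a large SD were Trgv3, Usp17ld, Prg2, Met, Mdga2, Mctp1, Cp, Smim5, Shisal2b, Gzmb, Avil and Trim35.

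In all, 516 genes varied more among the 9 ITD lines than within the control pairs, and the median SD was 0.199 among ITD lines, 0.124 within pairs and 0.173 between the means of the 3 IL-3-grown control lines. Against the pairs 4913 genes had an unadjusted p under 0.05. Of the 516 called genes only 268 had an ITD SD above the SD between control line means. The other called genes did not exceed the spread between control lines. The SD over single ITD arrays was above the SD between control line means for 59.6% of genes. At equal true spread an SD with 2 degrees of freedom has a lower median than one with 8. Neither this share nor the median SDs therefore show that mutants varied more than control lines. The F ratio against the spread between control lines gave no called gene and 1151 of 20227 genes at an unadjusted p under 0.05. With 2 degrees of freedom for the control lines this ratio could hardly call a gene, so whether mutants varied more than separately kept 32D lines stays open. Lines 4 and 7 stood apart, with 377 and 359 genes more than 2-fold from the median of the other lines, against 117 to 198 genes for the other 7 lines. The mean of the handling stress list was also highest in these lines, at 0.49 in line 4 and 0.40 in line 7 (log2, minus the mean of the 6 IL-3-grown control arrays), against -0.28 to 0.14 in the other ITD lines and at most 0.22 on the control arrays. The count fell to between 0 and 5 without any 1 of the 8 control arrays, and was 226 or 157 without ITD line 4 or 7. In line 4 Smim5 reached 9.51, beyond all 16 other arrays. Jun, a component of the AP-1 transcription factor and a member of the handling stress list, was highest in line 4 at 8.17 and nearly as high in line 7 at 8.10, against 5.80 to 7.59 in the other ITD lines. In line 5 Mdga2 and the stress-induced gene Nupr1 reached 8.59 and 10.76, and in line 7 Shisal2b reached 8.21. Genes named for a single line were picked for that distance.

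**Figure D3:**
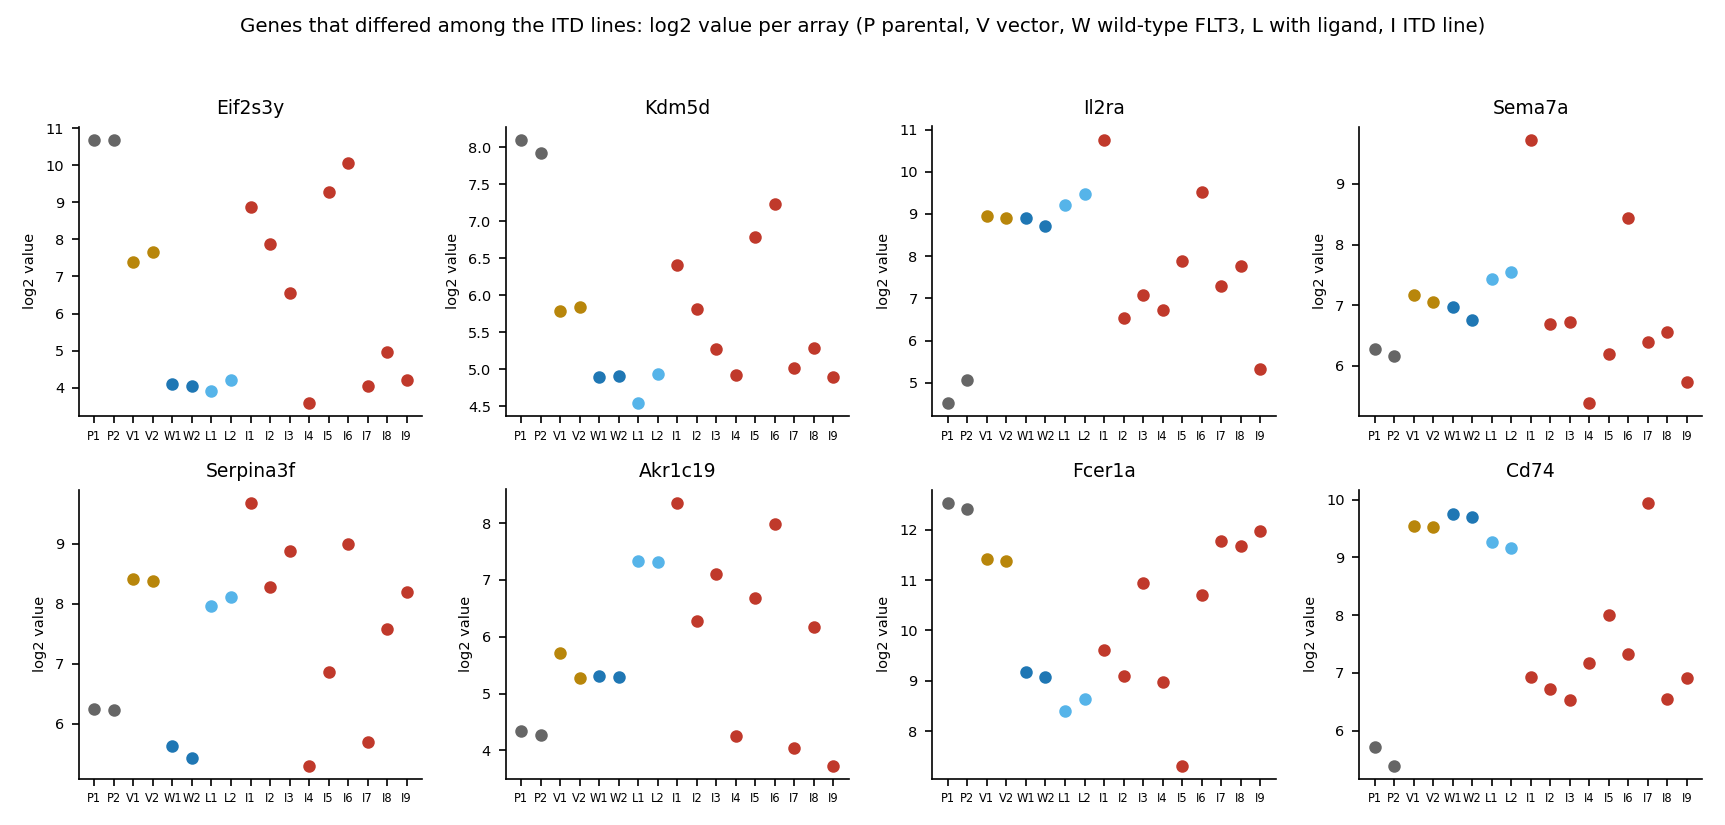
Log2 values of 8 genes (vertical axes) on each of the 17 arrays (horizontal axes, ordered by group; points are single arrays). Eif2s3y and Kdm5d, both Y-linked, were high on the parental arrays and ranged widely among the ITD lines, and Il2ra reached 10.76 in ITD line 1.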

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

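None of the tests in this part was chosen after the result was seen. For 141 named genes and the 21 list means, the line farthest from the other ITD lines was taken, and its gap to the nearest line was divided by the range of the 9 lines. Above Dixon's critical value for 9 values 15 genes and no list mean stood out, where chance gives about 1 in 20 even for genes without an unusual line, so several of the 15 may be expected from chance, and no explanation was tested. Gata1 and Klf1, transcription factors of the erythroid lineage, were lowest in ITD line 7, at 7.55 against 8.77 to 9.38 in the other lines (gap ratio 0.669) and at 6.30 against 7.29 to 7.89 (0.622). Ccne2 was also lowest in line 7, at 7.16 against 7.77 to 8.31 (0.531). The chemokine gene Ccl4, at 7.07 against 5.61 to 6.23 (0.576), Cd74, at 9.95 against 6.53 to 7.997 (0.572), and Ankrd22, at 7.47 against 5.80 to 6.56 (0.542), were highest in that line. Cd74, like Prg2 below, had been named for a large SD over the ITD lines, a choice that favoured this outcome. In line 4 the lowest were Pilrb1 at 7.07 against 8.61 to 9.77 (0.569), Adgre1 at 7.19 against 8.17 to 9.16 (0.498), and Trem1 at 4.40 against 5.32 to 6.27 (0.494). Insig1, a regulator of cholesterol synthesis, was lowest there too, at 8.82 against 9.40 to 9.89 (0.545). In line 5 Tespa1 was highest, at 7.45 against 4.73 to 5.97 (0.546), and Prg2 lowest, at 7.96 against 9.88 to 11.71 (0.511). In line 6 Chil1 was highest, at 7.47 against 6.22 to 6.77 (0.562), as was the coagulation factor gene F13a1, at 6.20 against 4.74 to 5.43 (0.526). Fdps of cholesterol synthesis was highest in line 9, at 9.29 against 8.48 to 8.87 (0.509).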

How the results depend on the processing

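The alternatives without the vector line, without the parental line, with lines as units, with crossed replicate numbers and without ITD lines 4 and 7 were chosen only after the results were seen. Most genes were named because they were called in the reported fit, a choice that favours agreement in other fits of the same arrays. Named genes kept their side of the threshold, and their direction where called, in 2625 of 2804 values for the first contrast, 658 of 670 against wild-type FLT3, 664 of 672 against wild-type with ligand, 452 of 472 for wild-type against vector and 447 of 471 for vector against parental. Genes named for variation among ITD lines did so in only 262 of 517 values, and the other 255 were no longer called, among them 18 of 20 with the median of probe sets and all 20 with the replicate block. For the first contrast, leaving out single arrays supplied 1426 of the 2625 unchanged values. With lines as units 42 of its named genes were no longer called, and 46 kept their side of the threshold. The reversals were Ptgs2 at -0.0181 with the stricter filter, Gata1 at -0.0848 against parental and vector cells only, Rtp4 at 0.327 without the vector line and Il3ra at 0.0782 without the parental line; the cause was not tested. The first contrast called 167 genes at 2-fold, 2491 without the vector line and 466 with lines as units, where fewer samples were used, and 2675 to 4792 without single arrays. Its gene lists called fell from 9 to 4 with an estimated correlation and were 9 to 11 without single arrays. At 2-fold, 292 genes were called against wild-type, 237 against wild-type with ligand, 328 for wild-type against vector and 184 for vector against parental. Array weights, which gave the ITD arrays 0.723 and the control arrays 1.44, raised the same counts to 3188, 2529, 3903 and 1937, and the ligand effect from 0 to 195. Without ITD lines 4 and 7 they were 2932, 1842, 2583 and 1077, with 111 for the ligand effect and 24 for variation. With only the control groups, whose spread within pairs may be technical, the ligand effect had 1148 genes, wild-type against vector 4652 and vector against parental 2773. Quantile normalisation again gave 681 genes for vector against parental, 1 for the ligand effect and 873 for variation. Variation among ITD lines, 516 genes as reported, had 317 without a filter, 1213 with the stricter filter, 50 with the median of probe sets, 0 with the replicate block and 0 against the spread between control lines; the cause was not tested, except that the last 2 leave fewer degrees of freedom. Leaving out single arrays gave 281 (without wild-type array 2; 308 without array 1) to 2463 (without ITD line 7) against wild-type. It gave 243 (without ligand array 1; 245 without array 2) to 1500 (without ITD line 5) against wild-type with ligand. The ligand effect had 0 to 4, with 4 without ITD line 5 and 1 each without line 4 and without line 9. Wild-type against vector had 456 to 2116, with 456 and 599 without wild-type arrays 1 and 2, and 516 and 503 without vector arrays 1 and 2. Vector against parental had 105 to 764, with 149 and 126 without parental arrays 1 and 2, 105 and 133 without vector arrays 1 and 2, and 764 without ITD line 7. Variation had 0 to 700, with 0 without either parental or ligand array, 1 without either wild-type array, 5 without either vector array, 226 without ITD line 4 and 157 without line 7. With the replicate block the other counts were 3595, 1335, 985, 0, 1448 and 352 in the order of the contrasts, and crossed replicate numbers gave 0 for the ligand effect. The filter on signal left out only probe sets with a mean of 4.599 or less over the 17 arrays, so genes close to background remained among the 20227 tested, and for these the arrays limit the size of a difference.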

Other observations

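The 3 tests of interferon genes and the splits for lists with an estimated correlation were chosen only after the results were seen. The receptor groups were also compared across all 20227 genes with differences that shared no array, and genes are not independent replicates. The difference of ITD from parental cells correlated with that of wild-type FLT3 from vector cells at r = 0.404 (Spearman's rho 0.36), with the same sign for 61.5% of genes. With the control lines exchanged, r was 0.134. The difference of ITD from parental and vector cells correlated at r = 0.101 with the effect of ligand on wild-type FLT3. Against parental cells alone 3439 genes were called for ITD and 2949 for wild-type FLT3, and 2838 for ITD against vector cells, while 235 genes were called in the same direction for ITD against parental, vector and wild-type cells alike.

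Kdm5d, a Y-linked gene named after its values were seen, followed Eif2s3y. Both were highest on the parental arrays, at 8.10 and 7.92 for Kdm5d, and lowest with wild-type FLT3 and in ITD lines 4, 7 and 9. A candidate explanation is loss of the Y chromosome from part of the cells. It predicted that the Y-linked genes move together, and the r between Eif2s3y and Kdm5d was 0.953 over the 17 arrays (rho 0.922, permutation p 1e-05, the smallest that the permutations can give, adjusted over 3 relations 3e-05) and 0.954 over the 9 ITD lines (rho 0.933, exact permutation p 2.2e-05, adjusted 6.6e-05, and r 0.945 without the 2 farthest lines). The permutation over 17 arrays treats the 2 arrays of each control group as independent, so its p may be too small. Reading of the X-linked copy by the probe sets was argued against by Eif2s3x, which spanned 0.679 (log2) over the 17 arrays against 7.10 for Eif2s3y. The r between them was -0.621 (-0.311 without the 2 farthest arrays, and 0.174 over the 9 ITD lines). Cells of a female line predicted higher Xist where Eif2s3y was lower, but Xist spanned only 0.859 (log2), with an r of -0.069. Xist rested on 2 probe sets and lay between 4.93 and 5.79, near background, so it cannot decide this question. No other Y-linked gene was analysed here, and the order of events in the cultures stays open.

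Interferon response genes were high on both vector arrays, with a list median of 1.61 ± 0.27 (bootstrap SE over 16 genes) above parental cells. Transduction as such was argued against by the other transduced lines, where the higher of the list medians was 0.324 ± 0.112 for wild-type FLT3, and that for ITD was 0.079 ± 0.109. These SEs measure spread between genes, not between lines. The list mean above parental cells ran from -0.213 to 0.541 over the ITD arrays, against 1.623 and 1.7 on the vector arrays. A response to transduction particular to the vector cultures cannot be judged from these values. Scaling of the arrays was argued against as well, since the lowest median under quantile normalisation and centring was 1.567. Cells of another type in the vector cultures cannot be told apart from a change in the 32D cells: the highest median among the monocyte, lymphoid and mast cell lists was 0.251 ± 0.122 for the monocyte list, within 2 SE of the bound of 0.403 that was set for it. What raised these genes in the vector line stays open.

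Il2ra, a known STAT5 target, differed among the ITD lines, and 3 relations with it were tested over the 9 lines. With the mean of the other STAT5 targets r was -0.325 (rho -0.3, exact permutation p 0.394, adjusted 0.591; r -0.581 without the 2 farthest lines). With Flt3 r was -0.034 (rho 0.25, exact permutation p 0.933, adjusted 0.933; r 0.467 without the 2 farthest lines). With Eif2s3y r was 0.67 (rho 0.633, exact permutation p 0.0453, adjusted 0.136; r 0.567 without the 2 farthest lines), which failed the correction. With 9 lines these explanations, STAT5 activity, transgene level and clonal differences, cannot be told apart, since the upper bounds of r (2 SE) were 0.446, 0.654 and 0.926.

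Other splits of the samples were fitted with 2 groups. The real split of 15 arrays into 9 ITD and 6 control arrays called 2096 genes, the highest of the other splits 8, and 1 of 100 splits, the real one, called as many. These splits treat the 2 arrays of a control line as independent, and chance can be excluded only if they are. For lists at the preset correlation the real split called 9, the highest other 12, and 6 of 100 splits called as many, so chance cannot be excluded for that number. For lists with an estimated correlation the real split called 1 and the highest other 0, and 1 of 100 splits called as many, a difference of 1 list that does not settle the question. With the 12 lines as units the real split called 466 genes and the highest other 545. Of the 220 possible splits 100 were drawn, and 2 of these, the real one included, called as many. This share is below 0.05, but not all splits were fitted, and another split called more genes than the real one. It argues against chance without excluding it. The split with 545 genes set ITD line 7 together with parental and vector cells against the other 8 ITD lines and wild-type FLT3.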
